A study of Mus musculus with 18 samples.

How the data were processed

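RNA was measured on 18 Illumina mouse bead arrays of 45281 probes each, 3 arrays in each of 6 groups. The groups crossed 3 mouse labels (1, 5 and 7) with 2 arms, cells given a short hairpin RNA (shRNA) against Foxd3 for 24 h and untreated cells. Per the labels, RNA was extracted with TRIzol and cleaned on RNeasy columns, and biotin-labelled cRNA was made with an Ambion kit. The labels did not say whether the 3 arrays of a group came from separate cultures.

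The deposited non-normalised table gave, for each array and probe, a signal intensity and a detection p-value. The deposited signal intensity had its background already subtracted, so that between 23.2% and 30.9% of the signals of an array lay below 0. The deposited detection p-value of a probe lay on a grid of 936 steps from 0 to 1. A deposited series matrix held a further signal intensity on a linear scale, each the non-normalised signal times 1 of 18 factors between 0.733 and 1.53. Those factors ran down the probes of each array in a repeating order of 18, which held for 285480 of the 285480 signals above 20 in size, so the matrix did not hold 1 scale per array and served as an alternative only. The software, its version and its settings were not given in the sources used here.

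Signals were background corrected from the detection p-values, quantile normalised and put on the log2 scale with neqc of limma 3.58.1 (offset 16) in R 4.3.3 with statmod 1.5.0. Probes with a detection p-value below 0.05 on at least 3 arrays were kept, which left 24817 probes, of which 11266 were detected on all 18 arrays. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6. Between 17289 and 19993 probes were detected per array. The number of arrays limited the precision.

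Gene symbols came from the probe annotation supplied with the series matrix. Of the 45281 probes, 34885 had 1 symbol, 18 had several and 10378 had none. Through the Entrez identifier, 34807 probes matched the RefSeq gene table of the mouse assembly GRCm38.p6, and 0 symbols changed. The tested probes with a symbol numbered 20829, for 12909 genes, those with a provisional name included. A gene was represented by its brightest probe.

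The effect of the shRNA across mice was tested on 6 profiles, the mean of the 3 arrays of each mouse label and arm, with treatment and mouse as terms (lmFit and eBayes with a trended prior variance). The mouse label thus paired the arms as a block. The effects within a mouse label, the treatment by mouse interaction and the differences between untreated cells were tested on the 18 arrays with 6 group means and 1 shared spread. Within a mouse label the p-values measured only the spread between arrays, which may be technical. That spread was pooled over the 6 groups, so it was not that of the label alone. All tests were two-sided, and p-values were adjusted by Benjamini and Hochberg over the 24817 probes, with a threshold of 0.05. The 3 array numbers of a group were not taken as pairs. Foxd3 itself was tested by exact permutation of the arrays within a mouse label and by an exact sign-flip over the mice, whether or not its probe passed the filter.

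The gene lists numbered 31, of which 19 were pathways and 12 were cell type markers. The pathway lists were Wnt targets, stem cell markers, pluripotency, neural crest, MAPK output, G2/M, G1/S, mesenchymal genes, epithelial genes, p53 targets, unfolded protein response, interferon, glycolysis and hypoxia, oxidative phosphorylation, cholesterol synthesis, NF-kappaB, ribosome biogenesis, Notch and hedgehog, and heat shock and oxidative stress. The marker lists were fibroblast or smooth muscle (called fibroblast below), endothelial, macrophage, T and NK cell, B and plasma cell, neutrophil, enterocyte, goblet, enteroendocrine, tuft, Paneth and erythroid. Lists with at least 3 measured genes were tested with camera (preset correlation 0.01), and again with an estimated correlation and with fry. The comparisons, the lists, the rule for named genes and the alternatives were chosen before the data were examined, except where stated. The rule named Foxd3 and Cdcp1, and across mice up to 12 rises and 12 falls past the threshold with the same sign in all 3 mice. It also named up to 4 genes per list, up to 5 rises and 5 falls per mouse label without overlap of the arms, and 6 genes of the interaction. Genes without a symbol or with a provisional name were counted and not named.

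The files were checked for irregular values after the first look at them. A probe was called irregular when a signal was printed in more than 7 digits, when a detection p-value lay off the grid by more than 0.002 of a step, or when it departed by more than 0.02 from the running median over 101 probes of similar signal. Markers of brown fat, skeletal muscle, liver and intestinal epithelium were listed only after the levels had been seen, 10 genes for each tissue.

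The models were tested on simulated data made from the probe means and array spread of the same 24817 probes, with 200 probes changed. Across mice, 95.5% of the changed probes were recovered at a log2 change of 1 and 99.5% at 2, with 6 and 20 false calls. There the simulated change had the same size in every mouse label, with array spread alone added. Recovery of changes that vary between labels was therefore not tested. For mouse 1 the shares were 75.0% and 98.0%, and for the interaction 39.0% and 93.0%. A shift of 0.5 in 1 of 29 lists was called, with 0 other lists called. The simulated probes varied independently of each other, so false calls of lists whose genes are correlated were not tested.

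Alternatives changed 1 choice at a time, except that the fits with mouse as a random block, with array weights, with array number as a block or with irregular probes left out on 18 arrays also replaced the 6 profiles across mice by 18 arrays. In addition, the series matrix values and the matrix factors applied once per array were used without the background correction and without quantile normalisation. They covered the block, the array weights, the background correction, the scaling, the offset, the detection filter, the trend, a fold minimum of 2, the series matrix and each mouse or array left out in turn. Alternatives added after seeing the data left out the irregular probes, left out array 2 of the untreated cells of mice 1 and 5, or applied the 18 matrix factors once per array. A block for the slide was not run because the file gave no slide.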

Results

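The series measured RNA in mouse cells that, per the labels, carried the surface protein CDCP1 and were pulled with antibody-coated beads out of colon tumours of 3 mice. The mice had 1 genotype, which includes a floxed allele of the tumour suppressor Apc, and were 17 weeks old. Cells were kept with doxycycline and were either given an shRNA against Foxd3, a forkhead transcription factor known from pluripotent and neural crest cells, or left untreated for 24 h. The 6 groups of mouse label and arm held 3 arrays each, 18 arrays in all. The mean signal of an array lay between 181 and 294 and the median between 5.24 and 10.9, with 17289 to 19993 probes detected. Values below are background-subtracted signals as mean ± SD (n = 3 arrays) unless stated, and changes are log2 values, shFoxd3 minus untreated. The SE of a change is the moderated standard error of limma, which draws on the spread of all probes.

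The targeted gene was near background on the arrays. The Foxd3 probe was detected on 1 of 18 arrays, with signals from -10.3 to 16.5. Its mean change was -0.06 ± 0.20 (SD, n = 3 mouse labels; exact sign-flip p = 0.75, two-sided, where 0.25 is the smallest p that 3 labels allow). The change was -0.11 in mouse 1, 0.16 in mouse 5 and -0.24 in mouse 7, with exact permutation p = 0.5, 0.2 and 0.2, where 0.1 is the smallest possible. A knockdown of Foxd3 was therefore not detectable in these signals. Cdcp1, the gene of the surface protein used for sorting, had 4 probes that were detected on 0, 1, 4 and 2 of the 18 arrays, with changes of -0.06, 0.00143, -0.05 and -0.05.

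The untreated cells were compared between the 3 mouse labels as a scale for the shRNA effect. Arrays labelled mouse 1 carried transcripts of brown fat, arrays labelled mouse 5 those of skeletal muscle and arrays labelled mouse 7 those of liver. Ucp1, the uncoupling protein of brown fat, had a signal of 10320 ± 3986 on the arrays of mouse 1, -4.6 ± 14.8 on those of mouse 5 and 8.4 ± 20.5 on those of mouse 7 (mean ± SD, n = 6 arrays of both arms). Myh4, a fast myosin heavy chain of muscle, had signals of 1487 ± 1697, 24295 ± 3024 and -4.2 ± 5.5 on the same arrays. Apoa1, an apolipoprotein of liver that is also in the enterocyte list, had signals of 12 ± 5.4, 9.9 ± 4 and 17366 ± 2024.

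Of 10 brown fat genes, 10, 6 and 2 were detected on all 6 arrays of mice 1, 5 and 7. Of 10 muscle genes the counts were 2, 10 and 1, and of 10 liver genes 1, 0 and 10. These tissue genes were chosen after their values had been seen. Epcam, an adhesion molecule of epithelial cells, was detected on 0 of the 18 arrays, with mean signals of 1.2, 3.6 and 0.2 in the 3 labels. Cdx2, a transcription factor of intestinal epithelium, had mean signals of 2.8, 11 and 4, and the actin-bundling Vil1 3.3, -1.9 and 6.7. Lgals4, a galectin of the gut, was detected on all 18 arrays, with mean signals of 482, 117 and 519, and the cadherin Cdh1 had 2.2, 13.7 and 357. Of the 20 epithelial genes on the array from the list fixed beforehand, 1, 1 and 9 were detected on all 6 arrays of mice 1, 5 and 7, and 1 was detected on all 18 arrays. Krt8, a keratin of simple epithelia, had mean signals of 5.2, 8.8 and 6147 in mice 1, 5 and 7.

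**Figure D1:**
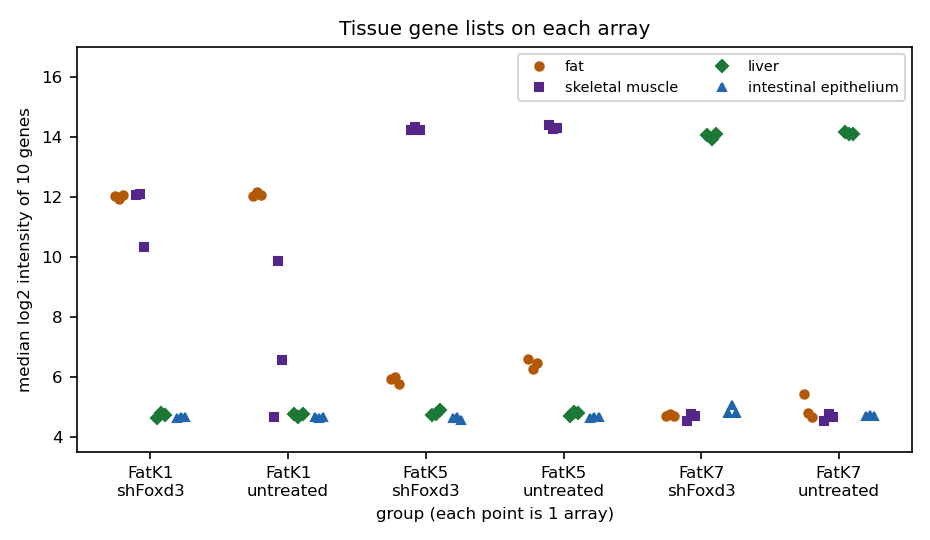
Median log2 signal intensity of 10 fat, 10 skeletal muscle, 10 liver and 10 intestinal epithelium genes (y axis) on each array of the 6 groups (x axis; FatK1, FatK5 and FatK7 are mouse labels 1, 5 and 7); each point is 1 array. Fat genes stand high on the arrays of mouse 1, muscle genes on those of mouse 5 and liver genes on those of mouse 7, and muscle genes spread from 4.66 to 9.86 on the untreated arrays of mouse 1.

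The limma F-test called 18268 of 24817 probes (73.6%) different between the untreated mouse labels, of which 10842 differed by at least 2-fold between the extremes and 2292 by at least 8-fold. The mouse label accounted for 90.2% of the variance of the 18 arrays, the treatment for 1.34% and the treatment by mouse term for 1.78%. The comparison holds for these 3 labels alone.

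Xist, the RNA that silences an X chromosome in female cells, and Eif2s3y, a gene of the Y chromosome, split the arrays within a mouse label. On 8 arrays Xist had signals of 664 to 1470 and Eif2s3y -11.1 to 8.31. On the other 10 arrays Eif2s3y had signals of 328 to 872 and Xist -13.3 to 13.6. The arrays of mouse 7 were all of the second kind. In mice 1 and 5, the shFoxd3 arrays and array 2 of the untreated cells had Xist, while arrays 1 and 3 of the untreated cells had Eif2s3y.

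**Figure D2:**
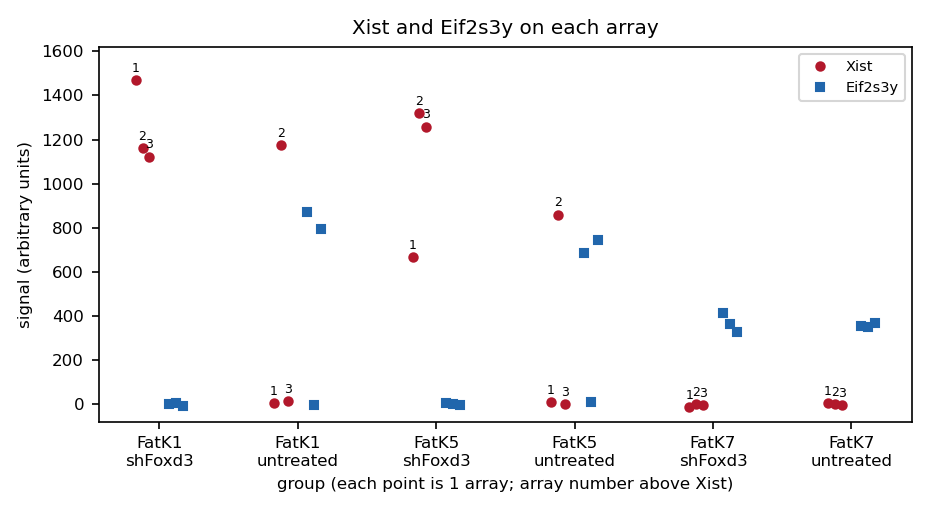
Signal of Xist and Eif2s3y (arbitrary units) (y axis) on each of the 18 arrays by group (x axis); each point is 1 array, with its number above Xist. In mice 1 and 5 the 2 genes part the untreated arrays, and the 6 arrays of mouse 7 have Eif2s3y and Xist near 0.

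Across the 3 mice, the question was which genes changed with Foxd3 shRNA. The called genes included goblet cell products and cyclins, which were higher with the shRNA, and a stem cell receptor and inhibitors of the cell cycle, which were lower. Muc2, the main mucin of goblet cells, rose by 2.77 ± 0.12 (moderated SE, n = 3 mouse labels, adjusted p = 0.000843). Tff3, a goblet cell trefoil peptide, rose by 2.52 ± 0.12 (adjusted p = 0.000843), and the cyclins Ccne2 and Ccna2 rose by 2.61 ± 0.12 and 2.50 ± 0.12 (adjusted p = 0.000843 for both). Lgr5, a receptor that marks intestinal stem cells, fell by 2.77 ± 0.15 (adjusted p = 0.000843). All probes called across mice carried irregular signals or detection p-values in the deposited table, these genes included, and 0 probes were called without them.

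The remaining rise was Birc5 (survivin), which acts in mitosis, at 2.65 ± 0.15 (adjusted p = 0.00106). Bmi1, a Polycomb protein of stem cells, fell by 2.62 ± 0.16 (adjusted p = 0.00151) and Ezh1, a histone methyltransferase, fell by 2.76 ± 0.17 (adjusted p = 0.00151). Rbpj, the transcription factor of Notch signalling, fell by 2.66 ± 0.18 (adjusted p = 0.00278). Among inhibitors of the cell cycle, Cdkn1a fell by 2.18 ± 0.21 (adjusted p = 0.0221), Cdkn1b fell by 2.66 ± 0.19 (adjusted p = 0.00396) and Cdkn1c fell by 2.14 ± 0.13 (adjusted p = 0.00151). The retinoblastoma genes Rb1 and Rbl1 fell by 2.25 ± 0.11 and 2.66 ± 0.20 (adjusted p = 0.000843 and 0.00405). Gadd45a, a stress gene, fell by 2.43 ± 0.12 (adjusted p = 0.000843). All 15 genes had the same sign in all 3 mice. For 11 of them, all but Cdkn1a, Cdkn1c, Rb1 and Gadd45a, the lower arm had mean signals of -0.55 to 42.1 per probe, low enough that their log2 changes, here and in the single mice, depend on the offset of 16 and are not exact sizes.

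In signal, Lgr5 stood at 6.16 ± 1.36 with shRNA and 157 ± 13.9 without in mouse 1, at 18.9 ± 2.04 and 213 ± 15.2 in mouse 5, and at 28.1 ± 17.0 and 281 ± 83.6 in mouse 7. Lgr5 was detected on none of the arrays of mouse 1 per the detection p-values, in spite of a signal of 157 there. A second Lgr5 probe was detected on 0 arrays and had a change of -0.01 ± 0.06 (SE). Cdkn1a stood at 2759 ± 618 and 11900 ± 3505 in mouse 1. Muc2 stood at 253 ± 121 and 23.4 ± 16.6 in mouse 1, and 1 other Muc2 probe, detected on 12 arrays, had a change of 0.01 ± 0.11.

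**Figure D3:**
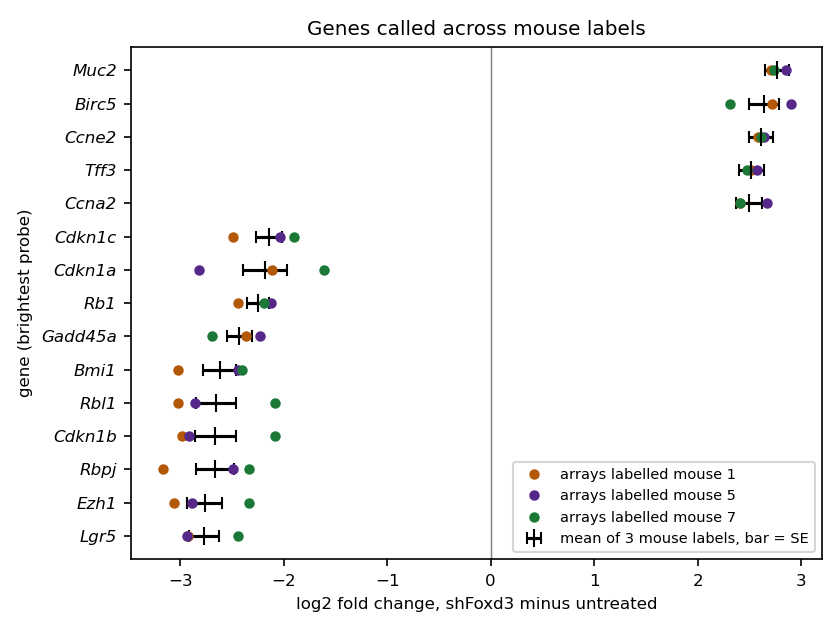
Log2 fold change, shFoxd3 minus untreated (x axis), of the 15 named genes called across mice (y axis). Points are the 3 mouse labels, the cross is their mean and the bar is the moderated standard error of limma, not that of the 3 points alone. The 5 rises and 10 falls have the same sign in all 3 labels, and the probes of all 15 carry irregular values.

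The limma fit called 26 of 24817 probes, 7 higher and 19 lower, and 1423 probes had an unadjusted p below 0.05. All 26 called probes were among the 46 probes of the array with irregular values (31 irregular probes were tested, Fisher's exact p = 3.78e-83, two-sided). Without the irregular probes, 0 probes were called. With 18 arrays and the mouse as a fixed term 38 probes were called, 8 of them regular, and 1 was called without the irregular probes. That probe, 1190007I07Rik, was named after its values had been seen and had a change of -1.35 ± 0.20 (adjusted p = 0.0455). Without the mouse block, 0 of the 26 calls were left. Without mouse 7, 50 probes were called, and without array 2 of the untreated cells of mice 1 and 5, 26 were.

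Of the 46 irregular probes, 43 held signals printed in more than 7 digits, 378 of the 815058 signals in the table. In 41 of them exactly 9 signals were so printed, all 9 in a single arm, which was the arm with the higher mean signal in each of the 41. That arm was shFoxd3 for 8 probes and untreated for 33. For 33 probes some detection p-values lay off the grid of the other probes, and 397 of these 426 values equalled 0.05. Every regular probe had a detection p-value of 0 above a signal that lay between 22.1 and 67.2 by array, while 268 irregular signals above that level had a p-value above 0. That level was set from the regular probes, and a departing p-value was itself a mark of irregularity. The contrast thus partly restates the rule, although 43 of the 46 probes were also irregular by their printed digits. A change of at least 2 was seen in 41 of the 46 irregular probes and in 4 of the 45235 regular ones, 2 probes of Xist (2.51 and 2.44), Eif2s3y (-2.35) and Gdpd3 (2.07), a phosphodiesterase. Regular probes of the genes with long-printed signals, 8 probes of 5 genes, had changes of -0.07 to 0.03, but only 1 was detected on at least 3 arrays.

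**Figure D4:**
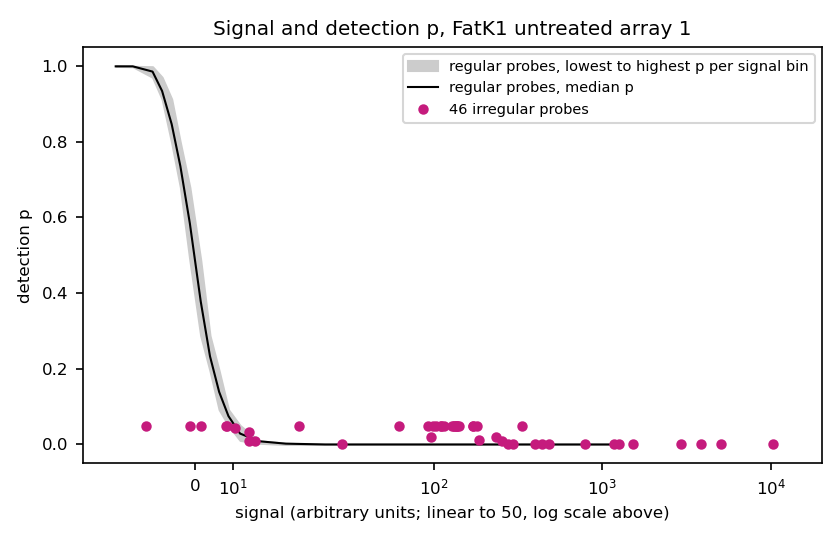
Detection p-value (y axis) against signal (x axis, arbitrary units, linear at low signals and logarithmic above) on array 1 of the untreated cells of mouse 1; the line is the median and the grey band the lowest to highest p-value of regular probes per bin of signal, and each point is 1 of the 46 irregular probes. Many irregular probes sit at 0.05 at signals where the regular probes are at 0.

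Gene lists were compared across mice to ask which processes and cell types moved. Genes of G2/M, the cell cycle stage before division, were higher with shRNA in all 14 measured members, with a median of 0.45 (camera adjusted p = 1.26e-12). Markers of macrophages were higher in all 10 measured members, with a median of 0.39 (adjusted p = 1.87e-05). Markers of fibroblasts or smooth muscle were higher in 13 of 14, with a median of 0.28 (adjusted p = 3.47e-05). Of 29 lists tested, 6 were called, 5 higher and 1 lower. With an estimated correlation 0 lists were called, at adjusted p = 0.77 for the G2/M, macrophage and fibroblast lists. The fry test of a shared direction called 0, with a lowest adjusted p = 0.197. Regardless of direction, fry gave adjusted p = 0.0269 for Wnt targets, 0.0171 for stem cell markers and 0.0171 for G2/M. It gave 0.00373 for G1/S and 0.0163 for heat shock and oxidative stress. Each of these lists held irregular members, and the other lists tested did not pass.

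In G2/M, 2 members rose, Ccna2 and Birc5, both with irregular values, 0 fell and 12 did not pass over all probes. Adjusted over the list alone, 7 rose, of which 5 were regular. Top2a, a topoisomerase of dividing cells, had a change of 0.52 ± 0.09 (adjusted p = 0.446), and the mitotic kinase Cdk1 0.61 ± 0.12 (adjusted p = 0.629). Without irregular probes the list had a median of 0.30 (adjusted p = 1.47e-07). With them its median was 0.15 in mouse 1, 0.62 in mouse 5 and 0.54 in mouse 7.

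Of the 10 macrophage markers 0 passed over all probes, and adjusted over the list alone 3 rose. The median was 0.19 in mouse 1, 0.23 in mouse 5 and 0.79 in mouse 7, and without mouse 7 the list had adjusted p = 0.0425. Csf1r, the receptor for a macrophage growth factor, had a change of 0.47 ± 0.11 and Adgre1, a macrophage surface protein, 0.64 ± 0.19 (adjusted p = 0.79 for both). Of the 14 fibroblast markers 0 passed over all probes, and adjusted over the list alone 1 rose, Thy1, a surface glycoprotein, with a change of 0.87 ± 0.12 (adjusted p = 0.22 over all probes). The collagen Col1a2 had a change of 0.73 ± 0.26 (adjusted p = 0.79). The fibroblast median was 0.53, 0.30 and -0.03 in mice 1, 5 and 7. Without irregular probes the adjusted p was 1.44e-05 for macrophage and 2.76e-05 for fibroblast markers.

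The lists of p53 targets, G1/S genes and B and plasma cell markers were also called. Of 17 p53 targets 13 had a negative change, with a median of -0.11 (adjusted p = 0.00657, and adjusted p = 0.77 with an estimated correlation). Over all probes and adjusted over the list alone 1 fell, Cdkn1a, with irregular values, while Trp53inp1, an autophagy gene, had a change of -0.58 ± 0.17 (adjusted p = 0.79). Of 19 genes of G1/S, the entry into DNA replication, 16 had a positive change, with a median of 0.08 (adjusted p = 0.0293, and adjusted p = 0.827 with an estimated correlation). Over all probes and adjusted over the list alone 1 rose, Ccne2, with irregular values. The 4 B and plasma cell markers had a median of 0.15 (adjusted p = 0.0414, and adjusted p = 0.77 with an estimated correlation), and 0 passed over all probes or adjusted over the list alone. Without irregular probes these 3 lists had adjusted p = 0.0622, 0.174 and 0.0577. Without mouse 5 they had adjusted p = 0.0638, 0.876 and 0.174, and without mouse 7 the B and plasma cell list had adjusted p = 0.213. From the series matrix the G1/S list had adjusted p = 0.0928 and the B and plasma cell list 0.065. The latter also had adjusted p = 0.155 with 18 arrays, 0.055 without background correction and 0.0524 without array 2 of the untreated cells of mice 1 and 5.

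The other 23 lists did not pass. Among 16 Wnt targets 1 fell, Lgr5, and 15 did not pass. Adjusted over the list alone 1 fell and 1 rose, Ccnd1, a cyclin, with a change of 0.63 ± 0.15 (list adjusted p = 0.317). Among 13 stem cell markers 2 fell, Lgr5 and Bmi1, over all probes and adjusted over the list alone, and 11 did not pass (list adjusted p = 0.307). Among 19 heat shock and oxidative stress genes 1 fell, Gadd45a, over all probes and adjusted over the list alone (list adjusted p = 0.746). The probes of Lgr5, Bmi1 and Gadd45a all had irregular values. In the next lists 0 members passed, over all probes or adjusted over the list alone. The list adjusted p was 0.964 for 10 pluripotency genes, 0.872 for 12 neural crest genes, 0.596 for 19 genes of MAPK output, 0.136 for 17 mesenchymal genes and 0.872 for 10 epithelial genes. It was 0.596 for 20 genes of the unfolded protein response, 0.479 for 18 interferon genes, 0.596 for 17 glycolysis and hypoxia genes, 0.596 for 22 genes of oxidative phosphorylation and 0.307 for 14 genes of cholesterol synthesis. It was 0.413 for 16 NF-kappaB genes, 0.596 for 17 genes of ribosome biogenesis and 0.734 for 16 Notch and hedgehog genes, of which Hes1, a Notch target, had a change of -0.63 ± 0.19 (adjusted p = 0.79). Among cell types it was 0.325 for 10 endothelial, 0.512 for 5 T and NK cell, 0.596 for 9 neutrophil, 0.869 for 8 enterocyte, 0.592 for 3 enteroendocrine, 0.596 for 5 tuft and 0.136 for 3 erythroid markers. Some of these lists passed under another setting at the preset correlation. An estimated correlation was run on the 6 profiles of the main fit alone, where it called 0 lists. The Wnt targets were lower with 18 arrays (adjusted p = 0.0463) or without the mouse block (adjusted p = 0.0106), and the stem cell markers without the block (adjusted p = 0.00211) or from the series matrix (adjusted p = 0.0127). With the irregular probes left out of the 6 profiles, the Wnt targets had adjusted p = 0.775, and the stem cell markers turned to higher with adjusted p = 0.607. With an estimated correlation both had adjusted p = 0.77. Without array 2 of the untreated cells of mice 1 and 5, the interferon list was lower (adjusted p = 0.0193), and the neutrophil and erythroid lists were higher (adjusted p = 0.0034 and 0.0132). The 14 cholesterol synthesis genes had medians of 0.15, 0.22 and -0.74 in mice 1, 5 and 7, with 0 of 14 positive in mouse 7. That list was lower without mouse 1 (adjusted p = 0.00176) or mouse 5 (adjusted p = 0.0123) and higher without mouse 7 (adjusted p = 0.00626). The NF-kappaB genes had medians of -0.30, -0.01 and 0.62, with 14 of 16 positive in mouse 7, and the list was higher without mouse 1 (adjusted p = 0.000379) and lower without mouse 7 (adjusted p = 0.0324). The neutrophil list was higher without mouse 1 (adjusted p = 0.000361), and the mesenchymal and oxidative phosphorylation lists were higher without mouse 7 (adjusted p = 0.0425 for both). Differences between mice were not tested for the lists. The goblet cell list, with 2 measured members that both rose over all probes and adjusted over the list alone (Muc2 and Tff3), and the Paneth cell list, with 1 (Lyz1, 0.21 ± 0.08, which passed alone), were too small to test. The probes of Muc2 and Tff3 both had irregular values.

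In the arrays labelled mouse 1, the question was the effect of shRNA in that label alone. Among called genes whose arms did not overlap, the 5 largest rises were genes of skeletal muscle. Pvalb, a calcium buffer of fast muscle, rose by 4.99 (adjusted p = 0.0012) from 524 ± 573 to 11760 ± 5618. The myosin light chain Mylpf rose by 4.80 (adjusted p = 0.00488), the creatine kinases Ckm and Ckmt2 by 4.65 each (adjusted p = 0.0092 and 0.00169) and troponin Tnnc2 by 4.65 (adjusted p = 0.0171). The shared spread behind these p-values took in the arrays of mice 5 and 7. There Pvalb stood at mean log2 levels of 14.5 in both arms of mouse 5 and of 4.68 and 4.72 in mouse 7. The p-values thus do not measure the spread of mouse 1 alone. The median log2 level of the 10 muscle genes was 4.66, 9.86 and 6.56 on the untreated arrays and 12.1, 12.1 and 10.3 on the shFoxd3 arrays. The 5 largest falls by the same rule, Rbpj (-3.17), Ezh1 (-3.06), Rbl1 (-3.03), Bmi1 (-3.02) and Cdkn1b (-2.98), all had irregular values. In all, 183 probes were called, 144 higher and 39 lower, of which 26 were irregular and 157 regular, and median scaling gave 197 higher and 24 lower. All shFoxd3 arrays and 1 of the 3 untreated arrays of this label had Xist. The count was 70 without shFoxd3 array 1, 84 without shFoxd3 array 2, 390 without shFoxd3 array 3, 289 without untreated array 2 and 80 without untreated array 3.

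The same question was asked of the arrays labelled mouse 5. Tiam1, an activator of the GTPase Rac, rose by 2.71 (adjusted p = 4.67e-07) from 71.4 ± 15.2 to 580 ± 189. The other named changes had irregular values. Birc5, Muc2, Ccna2 and Ccne2 rose by 2.90, 2.86, 2.67 and 2.65, and the changes of Lgr5, Cdkn1b, Ezh1, Rbl1 and Cdkn1a were -2.94, -2.92, -2.89, -2.86 and -2.82. In all, 62 probes were called, 27 higher and 35 lower, of which 25 were irregular and 37 regular. With median scaling 61 were higher and 24 lower. The median log2 level of the 10 brown fat genes, chosen after their values had been seen, was 6.59, 6.27 and 6.47 on the untreated arrays. It was 5.94, 5.98 and 5.77 on the shFoxd3 arrays. All shFoxd3 arrays and 1 of the 3 untreated arrays of this label had Xist. Without the irregular probes 22 were called, and the count was 112 without shFoxd3 array 3 and 267 without untreated array 1.

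In the arrays labelled mouse 7, with liver transcripts, serum amyloid genes, acute phase products of liver, were higher with shRNA. Saa1 rose by 4.09 (adjusted p = 4.06e-08) from 1378 ± 182 to 17070 ± 4616, and Saa2 by 3.71 (adjusted p = 3.45e-07) from 42.6 ± 7.06 to 955 ± 410. In mice 1 and 5 Saa1 lay near background (mean log2 4.65 to 4.76), and those arrays entered the shared spread behind its p-value. Mt2, a metal-binding protein, rose by 2.53 (adjusted p = 0.0152) from 74.2 ± 28.5 to 556 ± 168. Thrsp, a gene of fat synthesis, fell by 3.68 (adjusted p = 0.00347) from 3327 ± 1369 to 302 ± 323. Muc2 (2.74) and Ccne2 (2.61), Gadd45a (-2.69), Lgr5 (-2.44), Bmi1 (-2.40) and Ezh1 (-2.34) had irregular values. In all, 206 probes were called, 123 higher and 83 lower, of which 26 were irregular and 180 regular, and with 1 matrix factor per array 71 were higher and 88 lower. Without the irregular probes 124 were called, and the count was 113 without shFoxd3 array 1, 386 without shFoxd3 array 3, and 125, 100 and 94 without untreated arrays 1, 2 and 3.

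The probes called in all 3 mouse labels numbered 23, and all 23 were irregular. Across probes, the changes of mice 1 and 5 had r = 0.279, those of mice 1 and 7 r = 0.0351 and those of mice 5 and 7 r = 0.113. Without irregular probes these became 0.218, -0.0393 and 0.0287. Probes are not independent replicates.

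The treatment by mouse interaction asked whether the shRNA acted differently between mouse labels. Saa1, Saa2 and Saa3 had changes of 4.09, 3.71 and 1.90 in mouse 7, against 0.11, 0.08 and -0.43 in mouse 1 and -0.03, -0.02 and -0.12 in mouse 5 (adjusted p = 1.03e-05, 0.000187 and 0.00464). Tiam1 had a change of 2.71 in mouse 5, against 0.23 in mouse 1 and -0.21 in mouse 7 (adjusted p = 0.000226). Slc30a10, a manganese transporter, had a change of -1.24 in mouse 7, against -0.04 in mouse 1 and 0.09 in mouse 5 (adjusted p = 0.00211). Lrmda, a gene of melanocyte differentiation, had a change of 1.63 in mouse 1, against -0.03 in mouse 5 and -0.17 in mouse 7 (adjusted p = 0.00227). Apart from Tiam1, detected on all 18 arrays, these genes were detected on at most 1 array per group in the other 2 labels, so their changes there are values at background. The shared spread behind their p-values includes those background arrays. The limma F-test called 54 probes, of which 1 was irregular, with 2582 at an unadjusted p below 0.05. Without array 2 of the untreated cells of mice 1 and 5, the arrays that had Xist among untreated ones, 245 probes were called.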

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

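The tests on irregular values, on epithelial genes and on Xist and Eif2s3y were chosen only after the results had been seen, and the counts over other splits of the arrays were planned.

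The response to shRNA differed between the mouse labels for 54 probes by the test of the interaction. Saa1 (adjusted p = 1.03e-05), Saa2 (0.000187) and Saa3 (0.00464) stood apart in mouse 7, Tiam1 (0.000226) in mouse 5, Slc30a10 (0.00211) in mouse 7 and Lrmda (0.00227) in mouse 1. Apart from Tiam1, these genes were detected on at most 1 array per group in the labels they were set against, so that a lack of response there is not shown. When the arms were redrawn within each mouse label, 15 of 100 draws called as many probes, with a highest other count of 158, so that chance cannot be excluded for the count of 54.

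The first pattern is the set of 26 probes called across mice, all with irregular values. For the 18 dim probes (11 named genes), whose lower arm had a mean signal under 67.2, the level by which every regular probe had a detection p-value of 0, that signals and detection p-values are both as the arrays gave them is argued against by 122 signals above the level of their array with a p-value above 0, found in all 18 probes. For the 8 bright probes (of Cdkn1a, Rb1, Cdkn1c and Gadd45a, and 1 unnamed) there was 1 such signal. Their lower-arm means, 79.9 or more, already lay above 67.2, where a p-value of 0 goes with an unchanged and a raised signal alike. The count therefore cannot decide this for the bright probes, and it stays open. Signals rewritten after the array readout are consistent with the long-printed signals of 26 of the 26 probes. Whether the amount of RNA changed as well stays open, since 1 regular probe of the same genes, of Muc2, was detected on at least 3 arrays, and how the values came about is not shown by the files.

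The second pattern is the difference between the mouse labels. That the arrays hold sorted epithelial tumour cells of 1 kind is argued against by the epithelial genes fixed beforehand. Of these, 1 was detected on all 18 arrays. In mouse 7, 9 of 20 were detected on all 6 arrays, so that epithelial cells in that label are not excluded. Among those also listed for intestinal epithelium, Epcam and Cdx2 were detected on 0 arrays of mouse 7. Vil1, Cdx1, Krt19, Krt20 and Cdh17 were each detected on 1 array there, and Cdh1 on 6. The arrays of the 3 labels carried transcripts of different tissues, and RNA of different tissues as their source stays open as a hypothesis. The genes of brown fat, skeletal muscle and liver were chosen after their levels had been seen and cannot test it. A ranking of genes by mean signal used no such list. Among the brightest were the muscle genes Mylpf (25478) and Tnnc2 (25136) in mouse 5 and the liver gene Hpx (21983) in mouse 7. In mouse 1 the brightest was Hbb-bs (27905), which is not among the brown fat genes. Hbb-bs was also among the brightest in mouse 5 (26544), so it speaks neither for nor against brown fat in mouse 1. A sort for CDCP1 would remove cells without that protein. Whether the labels or the material were exchanged was not tested. Other biological differences between the mice stay open and untested.

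The third pattern is Xist and Eif2s3y within a mouse label. A response to the shRNA is argued against by 2 mouse labels whose untreated arrays are of both kinds. Arrays of more than 1 animal under 1 label are what 2 mouse labels show, since each held arrays of both kinds. In mice 1 and 5 alike, 4 arrays had Xist without Eif2s3y and 2 had the reverse, which argues against 1 animal per label there. In these labels the block by mouse label therefore did not pair arms of 1 animal. The arrays with Xist include all shFoxd3 arrays of mice 1 and 5, so in these labels the sex-linked difference moves with the treatment.

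For other splits of the samples, 3 of 10 splits of the 6 profiles called as many probes as the real one (26, highest other 141), and 5 of 10 as many lists (6, highest other 7). The other splits that called as many probes put both profiles of a mouse label on 1 side, which points to the structure of the samples. Among the splits that part all 3 mouse pairs, 1 called as many probes, the real one, and 3 as many lists, the real one included. The count of 6 lists is therefore not more than redrawn arms of the same pairs gave. Within mouse 1, 2 of 10 splits of the arrays called as many (183, highest other 231), within mouse 5 2 of 10 (62, highest other 99) and within mouse 7 1 of 10 (206, highest other 50). With 10 splits no share can fall below 0.05. For the untreated mice 1 of 100 draws, the real one, called as many as 18268 (highest other 12214). A random grouping of these arrays is thus argued against, with 1 in 100 the smallest share such draws allow.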

How the results depend on the processing

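Settings without the irregular probes, without untreated array 2 of mice 1 and 5, and with matrix factors per array were tests chosen after seeing the data. Where a cause is not stated below, the cause was not tested.

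Across mice, the 26 probes became 0 without the mouse block, 41 without a detection filter, 10 among probes detected on all 18 arrays (fewer probes tested) and 23 to 50 without 1 mouse. With 18 arrays in place of 6 profiles they became 38, and 40 with array weights added. Without irregular probes they became 0, since all 26 were left out. The 18-array count, with 8 regular probes, became 1, and the cause was not tested. With 18 arrays and mouse and array number as a block 29 were called. The array numbers were not taken as pairs, since r between arrays of a number ran from -0.0153 to 0.26. The other alternatives gave 25 to 34. Of the 15 named genes 0 were called without the mouse block, otherwise 13 to 15, and of 90 single-gene values 73 kept their side of the threshold, 17 fell short and 0 turned direction.

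With the 6 arrays of a mouse alone (fewer arrays, and the spread of that label alone), mice 1, 5 and 7 gave 37, 27 and 73 probes against 183, 62 and 206. With array number as a block they gave 298, 61 and 234. Leaving out 1 array gave 70 to 390, 65 to 267 and 94 to 386. Mouse 5 gave 22 without irregular probes and 41 with matrix factors per array. Mouse 7 gave 111 without background correction, 78 from the series matrix, 95 at 2-fold and 124 without irregular probes. The 54 interaction probes became 33 without background correction, 35 from the series matrix, 145 with array number as a block and 245 without arrays 2.

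The 6 gene lists became 0 with an estimated correlation, 0 with the fry test of a shared direction and 3 without irregular probes, and 4 to 9 otherwise. The untreated count of 18268 ranged from 15250 to 19959. The Foxd3 change ranged from -0.174 to 0.0229 at signals near background, which limits what it can show. Median scaling moved the median of all probes by up to 0.104 and the series matrix by up to 0.136. A slide block was not run since no slide is given, nor a replicate block for the untreated comparison, which has no arms.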

Other observations

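No tests are given here, and the genes were chosen only after their values had been seen. Acta1, the actin of skeletal muscle, ranged from 11.8 to 24037 over the 6 arrays of mouse 1 and had signals of 21569 ± 2482 (SD, n = 6 arrays) in mouse 5. Hpx, a heme-binding plasma protein, ranged from 18030 to 26670 over the 6 arrays of mouse 7.

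Tat, Hgd, Hpd and Fah, enzymes of tyrosine breakdown, were the remaining irregular probes. Fah had 1 signal printed in more than 7 digits, Tat and Hpd had detection p-values off the grid on 18 and 11 arrays, and Hgd had detection p-values that departed from the curve on 11 arrays.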
